A study of Mus musculus with 44 samples.

How the data were processed

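RNA sequencing was done on 44 bulk libraries from C57BL/6 mice in 12 groups. There were 4 libraries of sorted satellite glial cells (SGCs, the glia that wrap sensory neurons) and 4 of whole dorsal root ganglia (DRGs) from naive mice. There were 16 libraries of sorted SGCs after sham surgery or ligation of the sciatic nerve, 4 per surgery at 3 days and 4 per surgery at 14 days. There were 20 libraries of isolated neurons 8 days after surgery: 3 per sex and surgery, and 4 each from the ligated side and the opposite side of ligated mice. Per the labels' protocols, SGCs came from enzymatically dissociated, paraformaldehyde-fixed and antibody-stained L3 and L4 ganglia sorted by flow cytometry. The naive DRG libraries were dissociated and fixed but not sorted, and the neurons were isolated with magnetic beads from L3 to L5 ganglia and were not fixed. Per the labels, the SGC mice had a full ligation and the neuron mice a partial one. No label says which libraries come from the same animal or whether a library pools animals, so every p-value measures only the spread between libraries.

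Per the submitters' processing notes, the authors used STAR, SAMtools, Cufflinks and DESeq2 with the mouse build mm10, with no versions, order or roles given. Expression was deposited as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) in 3 tables: naive SGCs with DRGs, SGCs after surgery, and neurons. The FPKM tables were scaled separately, so levels in different tables are not on 1 scale. The naive and SGC surgery tables each held 45952 lines for 45882 genes, of which 44952 Ensembl identifiers were matched to GENCODE M21 names. The neuron table held 12181 lines for 12170 genes, of which 12121 were matched, and lacks several glial genes such as Gja1 and Kcnj10. Lines that shared an identifier with another line (121 in each of the larger tables) had their FPKM values summed per identifier. The authors' deposited tables of differential expression give, per the file headers, a baseMean, a log2 fold change with its standard error and an adjusted p-value for 46078 lines each. Of these 4 tables, 3 name their comparison: SGCs at 3 days, SGCs at 14 days and neurons at 8 days. In these, a negative log2 fold change means higher after ligation: of the genes past the authors' adjusted p-value of 0.05 and tested here, 121 of 122, 152 of 153 and 223 of 223 had the opposite sign in the FPKM values. The text gives the authors' fold changes as ligated over sham. The fourth table names no comparison.

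The deposited files hold no read counts and no library totals, so depth per library is unknown and no counting interval can be given. The baseMean values in the authors' deposited tables sum to 17802375, 18932928 and 22889482 for SGCs at 3 days, SGCs at 14 days and neurons. Between 11441 and 13173 genes reached 1 FPKM in the libraries of the naive table, 11452 to 12775 in those of the SGC surgery table, and 10225 to 11004 in the neuron libraries. No pair of libraries was identical. Exact zeros occur for genes that most cells use, so a gene is described only as listed at 0.

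Expression was tested with limma 3.58.1 in R 4.3.3 (linear model with a mean-variance trend, two-sided moderated test) on log2(FPKM + 1). A fold change on this scale understates the change of genes at low FPKM. Genes needed at least 1 FPKM in as many libraries as the smallest group of the fit. All groups of a table shared 1 fit, and p-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison. A gene is called when its adjusted p is under 0.05. There were 10 comparisons. Those of SGCs were naive against DRGs, ligated against sham at each day, the difference between these effects, and sham at 14 against 3 days. Those of neurons were ligated against sham over both sexes and in each sex, the difference between the sexes, and ligated against opposite side. The comparison over both sexes took the mean of the male and the female difference, with no covariate. Where no gene differs, a share of about 0.05 of the genes tested has an unadjusted p under 0.05. Of the counts given below, only those of SGCs at 3 days and of the ligated against the opposite side clearly exceed that share. Python 3.11.15 with pandas 2.3.3 made the tables and Matplotlib 3.10.9 the figures.

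Before the data were examined, 28 gene lists were fixed from textbook knowledge. Cell type markers covered satellite glial cells, myelinating and repair Schwann cells, neurons, nociceptors, large-diameter sensory neurons, macrophages, lymphocytes, neutrophils, endothelial cells, fibroblasts, mural cells and erythrocytes. The other lists were cholesterol synthesis and uptake, fatty acid synthesis, fatty acid oxidation and PPAR targets, the nerve injury response of neurons, neuronal ion channels and receptors, reactive glia, cytokines and chemokines, interferon response, antigen presentation, complement, cell cycle, extracellular matrix, gap junctions with glutamate and potassium buffering, immediate early and dissociation genes, and mitochondrially encoded genes. Lists were tested against the other genes with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusting over the lists of a comparison. Fry tests whether a list's genes move on balance in 1 direction and does not compare them with other genes. List members were also counted after adjustment over the list alone.

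The rule for named genes was fixed at the same time. It took the 8 largest rises and 8 largest falls among called genes with a fold of at least 2 and no overlap between libraries, passing over predicted, ribosomal and mitochondrial genes. Where none passed, it took the 3 smallest p-values in each direction. It added up to 4 members of each list, Fabp7, Glul, Kcnj10, Gja1, Gfap and Atf3 in every comparison, and 5 sex-linked genes in neurons. Genes chosen by the same rule among those above 0 in every library were added after the data were seen, since several of the largest differences were genes listed at 0 in a whole group.

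Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, quantile normalization, limma array weights, only the groups compared in the fit, the replicate number as a block, each library left out in turn, a fold of at least 2, and the authors' own counts. A fit on genes above 0 in every library was added after the data were seen. The tests were tried first on simulated tables with known changes, where a log2 change of 2 was recovered for 93% of changed genes in the naive comparison, 82% in SGCs at 3 days, 72% in SGCs at 14 days and 96% in neurons over both sexes. For a log2 change of 1 the shares were 47%, 36%, 35% and 46%. The changed genes were drawn from those with a mean log2(FPKM + 1) of at least 2, and the spread was shuffled gene by gene. These shares therefore cover neither genes at low FPKM nor correlation between genes. Gene positions are from GENCODE M21 (GRCm38, mm10); of 12132 neuron table lines with a position and a matched identifier, 12132 had the same chromosome there and 99.86% an overlapping span.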

Results

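The data set covers 3 cell preparations of mouse dorsal root ganglia, where sensory neurons have their cell bodies wrapped in SGCs. Naive mice gave 4 SGC and 4 whole DRG libraries, each sequenced over 3 lanes. Sciatic nerve ligation or sham surgery gave 4 SGC libraries per surgery at 3 and at 14 days. Isolated neurons at 8 days gave 20 libraries, each sequenced over 2 lanes. The total reads per library are not in the files. Values are FPKM as mean ± SD over libraries, and differences are on the log2(FPKM + 1) scale with the limma adjusted p.

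The first comparison asks which genes mark sorted SGCs against the whole ganglion. Genes of glial support functions were higher in the sorted cells and neuronal genes far lower. Fabp7 (ENSMUSG00000019874, chromosome 10, 57784881 to 57788450, GRCm38), a fatty acid binding protein of immature and satellite glia, stood at 13717 ± 2534 FPKM in SGCs and 3924 ± 760 in DRGs (n = 4 each). Its log2 difference was 1.80 ± 0.21 (SE; adjusted p = 0.000199). Gja1, the gap junction protein connexin 43, rose by 1.85, from 36.8 ± 9.65 FPKM in DRGs to 133 ± 15.3 in SGCs (n = 4 each, limma adjusted p = 0.00012). The potassium channel Kcnj10 was higher by 1.35 (67.2 ± 8.49 against 25.8 ± 4.07 FPKM), and glutamine synthetase, Glul, by 1.05 (152 ± 8.17 against 72.9 ± 7.49). The intermediate filament Gfap stayed under 1 FPKM in all 8 libraries and was not tested.

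Of the 15 satellite glial markers, 14 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 1.40. Cdh19 rose by 1.38, the endothelin receptor Ednrb by 1.48 and Ttyh1 by 1.56. The list test gave an adjusted p of 3.57e-08 by camera, and an adjusted p = 0.125 with an estimated correlation. Gap junction, glutamate and potassium buffering genes had 7 members higher and 1 lower of 11, among them the water channel Aqp4 at 1.58 (camera adjusted p = 0.00271; adjusted p = 0.151 with an estimated correlation).

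Lipid synthesis genes were higher in SGCs. Of 22 cholesterol synthesis and uptake genes, 15 rose and none fell, over all genes and adjusted over the list alone (median 0.77). Hmgcs1 stood at 420 ± 29.9 FPKM in SGCs against 184 ± 15.2 in DRGs (n = 4 each), a log2 difference of 1.18 (limma adjusted p = 8.68e-05). Cyp51 rose by 0.95 and Insig1, a regulator of the pathway, by 1.70. Of 11 fatty acid synthesis genes, 10 rose by both adjustments (median 0.90), with Scd1 at 1.22, Scd2 at 1.09 and Fads1 at 1.20. Of 10 fatty acid oxidation and PPAR target genes, 5 rose over all genes and 6 adjusted over the list alone, Angptl4 by 1.07 (median 0.44). Camera gave adjusted p of 6.27e-07, 2.45e-05 and 0.00187 for these 3 lists, and each had an adjusted p = 0.125 with an estimated correlation.

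Interferon response genes had 15 of 18 members higher and none lower by both adjustments (median 1.12; camera adjusted p = 2.5e-06, adjusted p = 0.21 with an estimated correlation). Ifitm3 rose by 1.26 over the ganglia. Antigen presentation genes split: 6 rose and 4 fell of 11, with B2m, the light chain of class I molecules, higher by 1.44 and the class II genes H2-Aa and Cd74 lower (−5.26 and −5.15). Their median was 0.63 and their mean −0.97, and the list did not pass (camera adjusted p = 0.418). Extracellular matrix genes had 7 members higher and 3 lower of 15 over all genes, and 8 and 4 adjusted over the list alone (median 0.77; camera adjusted p = 0.00727, adjusted p = 0.267 with an estimated correlation). The basement membrane genes Nid1 and Lamc1 rose by 1.45 and 1.23 and the protease gene Mmp14 by 1.32. Immediate early and dissociation genes, which tissue handling induces, had 9 members higher and 1 lower of 14 (10 and 1 adjusted over the list alone; median 0.68). Hspa1a rose by 1.10 and Fos by 0.87 while Atf3 fell by 1.43 (camera adjusted p = 0.00271, adjusted p = 0.315 with an estimated correlation). Among genes above 0 in every library, the largest rises were in Plscr2 (2.03), the Notch ligand Jag1 (2.01) and the receptor Lgr4 (1.97), chosen after the values were seen.

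**Figure D1:**
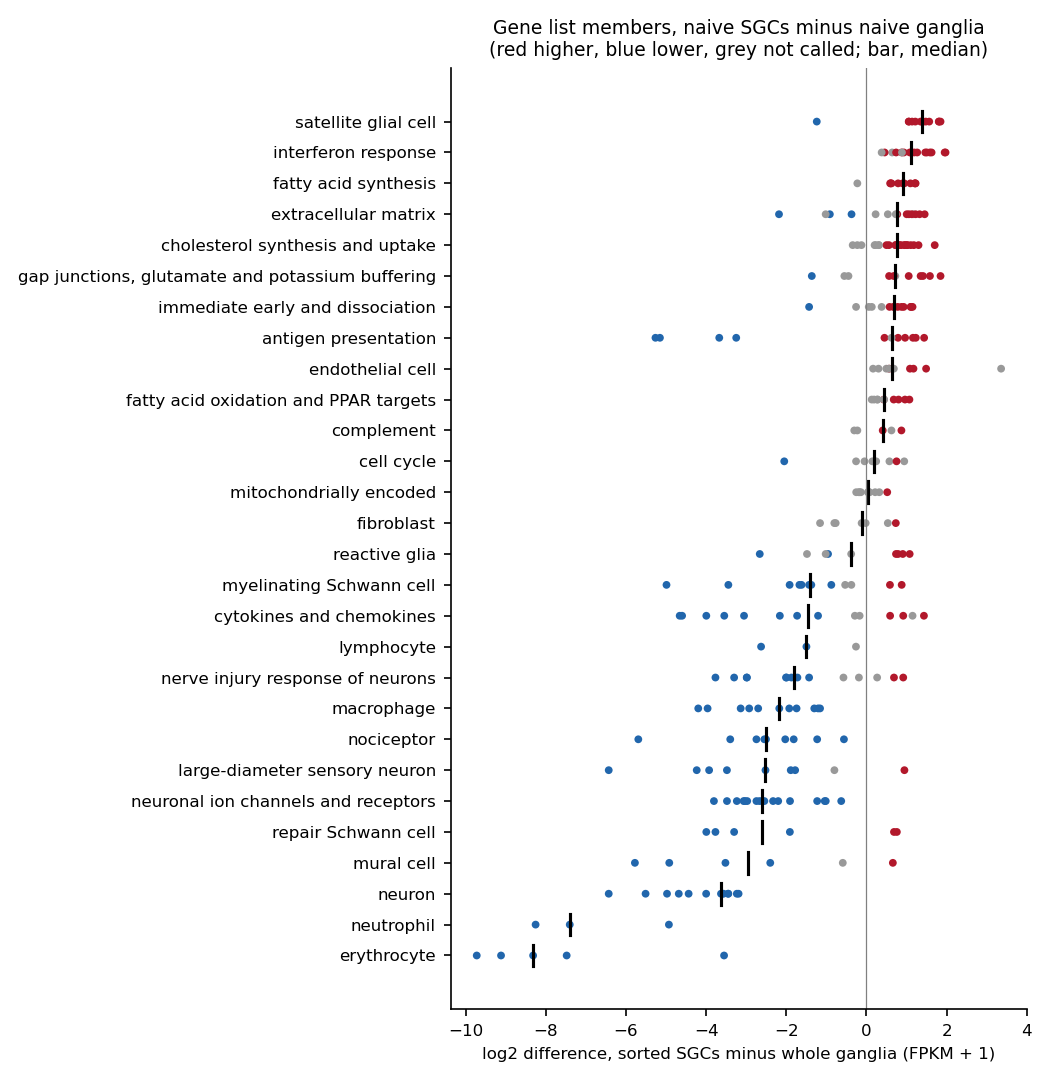
Each point is a tested member of a gene list, placed by its log2 difference between sorted SGCs and whole ganglia from naive mice (n = 4 libraries each). Black bars are list medians, from 1.40 for satellite glial markers to −8.32 for erythrocyte markers.

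Neuronal genes fell in the sorted cells. All 13 tested neuron markers fell (median −3.63), as did 9 of 9 nociceptor markers (−2.51), 7 of 9 large-diameter neuron markers (−2.52, with 1 higher) and 17 of 17 neuronal ion channels and receptors (−2.60), by both adjustments. The neurofilament Nefm stood at 10.8 ± 2.72 FPKM in SGCs and 556 ± 185 in DRGs (n = 4 each), a log2 difference of −5.51 (limma adjusted p = 6.78e-06). Calca, which encodes the peptide CGRP, fell by 5.69, the surface protein Thy1 by 5.50, Map7d2 by 5.33, Nefh by 6.43, the sodium channel Scn10a by 2.75, Ntrk3 by 3.93, the potassium channel Kcna1 by 3.03 and the serotonin receptor Htr3a by 3.81. Camera gave adjusted p of 6.26e-08, 0.000283, 0.00212 and 3.57e-08, and adjusted p of 0.198, 0.105, 0.125 and 0.125 with an estimated correlation. Nerve injury response genes had 2 members higher and 9 lower of 14 (median −1.80; camera adjusted p = 0.0253, adjusted p = 0.125 with an estimated correlation).

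Markers of most other cells of the ganglion fell too. Hbb-bs was listed at 0 in 2 SGC libraries and stood at up to 0.704 FPKM in the others, against 644 to 1391 in the 4 DRG libraries, and all 5 erythrocyte markers fell (median −8.32). S100a9 was listed at 0 in all 4 SGC libraries against 151 to 181 FPKM in DRGs, S100a8 and Hba-a1 fell by 8.25 and 9.12, and all 3 neutrophil markers fell (median −7.40). All 11 macrophage markers fell (median −2.18), with Tyrobp at −3.96 and C1qb at −2.70. Mural markers had 4 members lower and 1 higher of 6 over all genes, and 5 and 1 adjusted over the list alone (median −2.96), with Acta2 at −4.92 and Rgs5 at −3.52. Myelinating Schwann markers had 8 lower and 2 higher of 12, and 9 and 2 adjusted over the list alone (median −1.40). Pmp22 was at 243 ± 12.4 FPKM in SGCs against 782 ± 102 in DRGs (n = 4 each), and Ncmap fell by 4.99. Camera gave adjusted p of 1.09e-05, 6.93e-05, 3.93e-06, 0.00716 and 0.0061 for these 5 lists. Their adjusted p with an estimated correlation were 0.125, 0.125, 0.105, 0.149 and 0.329. Endothelial markers went the other way: 4 of 10 rose by both adjustments, Cdh5 by 1.49 and Flt1 by 1.09 (median 0.63; camera adjusted p = 0.00212, adjusted p = 0.267 with an estimated correlation).

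Other lists did not pass camera. Repair Schwann markers had 4 lower and 2 higher of 6 (adjusted p = 0.128), with Ngfr at −4.00 and Gap43 at −3.77. Lymphocyte markers had 2 lower of 3 (0.0664), cytokines and chemokines 8 lower and 3 higher of 14 (0.16), and fibroblast markers 1 higher of 7 (0.667). Il18 rose by 1.43 and the collagen gene Col1a2 by 0.73. Reactive glia genes had 4 higher and 2 lower of 9 over all genes, and 4 and 4 adjusted over the list alone (adjusted p = 0.628), with Vim at 1.08 and the protease inhibitor Serpina3n at −0.96. Complement genes had 2 higher of 5 (0.272), C4b by 0.87, cell cycle genes 1 higher and 1 lower of 8 (0.352), and mitochondrially encoded genes 1 higher of 11 (0.418), none adjusted over the list alone. For reactive glia and fibroblast markers camera pointed up while median and mean were below 0.

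Over all 12907 genes tested, limma called 2184 higher and 3605 lower in SGCs, and 814 and 2302 with a fold of at least 2. The median of all genes was −0.12. Quantile normalization moved it to 0.16 and turned the split to 3701 higher and 2691 lower, while each gene named in this comparison kept its direction. The 8 largest rises were genes listed at 0 in all 4 DRG libraries, such as Iqcc (130 to 168 FPKM in SGCs), Pigp (115 to 126) and Becn1 (14.1 to 19.2).

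The next comparison asks what changed in SGCs 3 days after nerve ligation. Genes that injured sensory neurons switch on were higher, and cholesterol synthesis genes were lower. Gal (ENSMUSG00000024907, chromosome 19, 3409915 to 3414544, GRCm38), which encodes the neuropeptide galanin, stood at 1402 ± 543 FPKM after ligation and 71.1 ± 86.1 after sham surgery (n = 4 each). Its log2 difference was 5.19 ± 0.82 (SE; limma adjusted p = 0.0333). Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039), an injury-induced transcription factor, stood at 64.2 ± 20.1 against 6.29 ± 4.68 FPKM (n = 4 each), a difference of 3.36 ± 0.51 (limma adjusted p = 0.0331). The transcription factor Sox11 rose by 2.95 (adjusted p = 0.0331), Stmn4, a tubulin-binding stathmin, by 2.85 (0.0457) and the adhesion protein Flrt3 by 1.55 (0.0331).

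Of 18 tested genes of the nerve injury response, these 5 rose over all genes, 11 rose adjusted over the list alone, and 17 of 18 had a positive difference (median 1.54). The list passed camera (adjusted p = 3.1e-17; adjusted p = 0.0334 with an estimated correlation). The authors' deposited table has 8 of its members higher after ligation. Gap43, a growth cone protein, was at 201 ± 88.2 against 43.1 ± 20.5 FPKM (n = 4 each; 2.27, limma adjusted p = 0.172). Neuron markers as a list had a median of −0.15 and a mean of 0.03 and did not pass (camera adjusted p = 0.836), with Stmn2 at 1.33 (adjusted p = 0.331). Nociceptor markers had 7 of 8 members negative (median −0.94), Calca at −1.25 with adjusted p = 0.682. Neuronal ion channels had 12 of 13 negative (median −0.52), Kcna2 at −0.56 with adjusted p = 0.283. Camera gave adjusted p of 0.00581 and 0.00105 for these lists, and each had an adjusted p = 0.355 with an estimated correlation.

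Of 22 cholesterol synthesis and uptake genes, 2 fell over all genes, 14 fell adjusted over the list alone, and 21 had a negative difference (median −0.58; camera adjusted p = 1.58e-19, adjusted p = 0.00166 with an estimated correlation). Lss (ENSMUSG00000033105, chromosome 10, 76531588 to 76557138), which makes lanosterol, stood at 14.1 ± 1.08 FPKM after ligation and 31.0 ± 8.7 after sham surgery (n = 4 each), a difference of −1.05 ± 0.17 (limma adjusted p = 0.0457). Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260) stood at 217 ± 12.4 against 360 ± 39.3 FPKM (n = 4 each), a difference of −0.72 ± 0.11 (limma adjusted p = 0.0333). By the authors' deposited table, 9 members are lower after ligation past an adjusted p of 0.05. Of 11 fatty acid synthesis genes none was called over all genes and 4 fell adjusted over the list alone (median −0.24; camera adjusted p = 0.00105, adjusted p = 0.117 with an estimated correlation).

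Endothelial markers moved with these groups: all 10 had a positive difference (median 0.75) and 1 rose adjusted over the list alone (camera adjusted p = 6.02e-06, adjusted p = 0.222 with an estimated correlation). Egfl7 was at 134 ± 37.5 against 79.6 ± 15.8 FPKM and Vwf at 75 ± 21.5 against 38 ± 28.2 (n = 4 each). Reactive glia genes had none called over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.00581, adjusted p = 0.122 with an estimated correlation). Serpina3n was at 158 ± 18 against 94.6 ± 24.2 FPKM (0.76, limma adjusted p = 0.162). Immediate early genes passed camera with Atf3, which is also on the injury list, as the member called (adjusted p = 0.0391, adjusted p = 0.6 with an estimated correlation). Satellite glial markers did not pass (median −0.08, camera adjusted p = 0.221), with Fabp7 at −0.23 and Kcnj10 at −0.28.

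**Figure D2:**
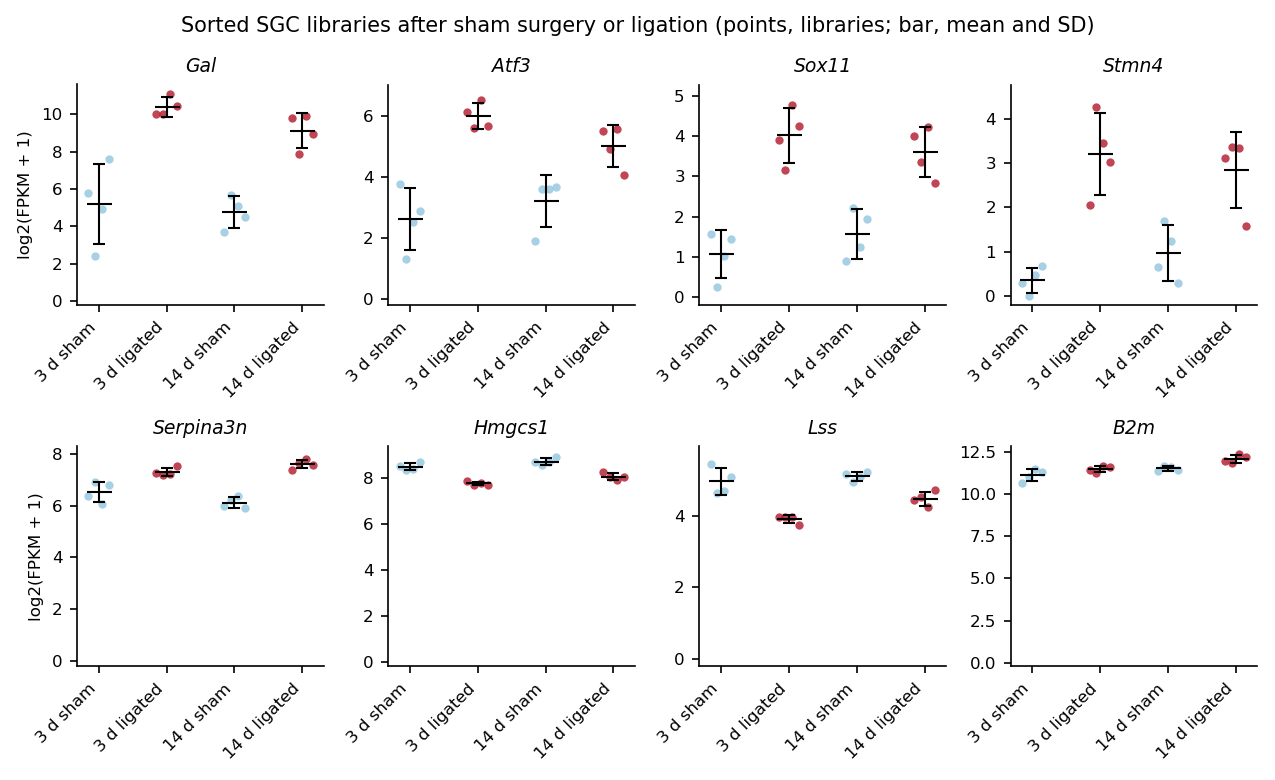
Points are log2(FPKM + 1) of single SGC libraries after sham surgery (blue) or ligation (red) at 3 and 14 days (n = 4 each); black bars are mean and SD. Gal, Atf3, Sox11 and Stmn4 are higher after ligation and Hmgcs1 and Lss lower at 3 days, and Serpina3n is higher at 14 days.

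Over 13924 genes, limma called 6 higher and 3 lower at 3 days, and 1269 had an unadjusted p under 0.05. The other called genes, which were chosen after their values were seen where the rule did not name them, were Polr2b and Snora21. Polr2b was listed at 0 in all 4 ligated libraries against 4.73 to 6.54 FPKM in sham, and Snora21 was listed at 0 in all 4 sham libraries against 87.5 to 847 FPKM. In the authors' deposited table Polr2b has a log2 fold change of −0.31 and an adjusted p of 0.819, and Snora21 has a baseMean of 1.46 and no adjusted p, so its FPKM values rest on few reads. Quantile normalization gave 7 higher and 1 lower. With no filter on low values the count was 1, with a pseudocount of 0.1 it was 14, with array weights 5 and with only the groups compared 4. It also rests on few libraries: it fell to 1 without sham replicate 2, without sham replicate 3 or without ligated replicate 4. It was 5 without sham replicate 1 or 4, 4 without ligated replicate 2 and 3 without ligated replicate 3. The authors' deposited table holds 179 genes past 0.05, 88 higher and 91 lower after ligation, and 7 of the 9 genes called here are among them.

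At 14 days after ligation, 1 gene passed over all genes: Serpina3n (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), a protease inhibitor on the reactive glia list. It stood at 195 ± 23.1 FPKM after ligation and 69.2 ± 10.1 after sham surgery (n = 4 each), a log2 difference of 1.49 ± 0.18 (limma adjusted p = 0.0066). In the authors' deposited table its log2 fold change is 1.52 with an adjusted p of 3.02e-19. Serpina3n is not particular to glia in these data. It was lower in naive sorted SGCs than in whole ganglia. Isolated neurons of male sham mice held 208 ± 44.3 FPKM (n = 3), on a separate scale. Which cells gave the rise was not tested. All 9 tested reactive glia genes had a positive difference, 1 over all genes and 2 adjusted over the list alone rose, and the list passed camera (median 0.38, adjusted p = 6.23e-07; adjusted p = 0.00874 with an estimated correlation).

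The injury response and cholesterol lists moved at 14 days as well. Of 18 nerve injury response genes, 12 rose adjusted over the list alone and none over all genes, with 17 positive (median 1.29; camera adjusted p = 1.99e-19, adjusted p = 0.0144 with an estimated correlation). Gal was at 637 ± 337 against 29.5 ± 16.8 FPKM (n = 4 each; 4.37, limma adjusted p = 0.2), Atf3 at 33.8 ± 14.4 against 9.18 ± 4.29, and Gap43 at 196 ± 97.3 against 38.9 ± 17.3. By the authors' deposited table, 9 members are higher after ligation, Gal by 4.47 with an adjusted p of 5.2e-12. Neuron markers had a median of 0.23 and did not pass (camera adjusted p = 0.102), with Stmn2 at 1.22 (adjusted p = 0.839). All 22 cholesterol genes had a negative difference (median −0.49), and 15 fell adjusted over the list alone and none over all genes (camera adjusted p = 2.67e-21, adjusted p = 0.0011 with an estimated correlation). Hmgcs1 was at 269 ± 30.1 against 423 ± 39.9 FPKM and Msmo1 at 220 ± 51.1 against 342 ± 30.6 (n = 4 each). The authors' deposited table lists 7 members as lower after ligation.

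**Figure D3:**
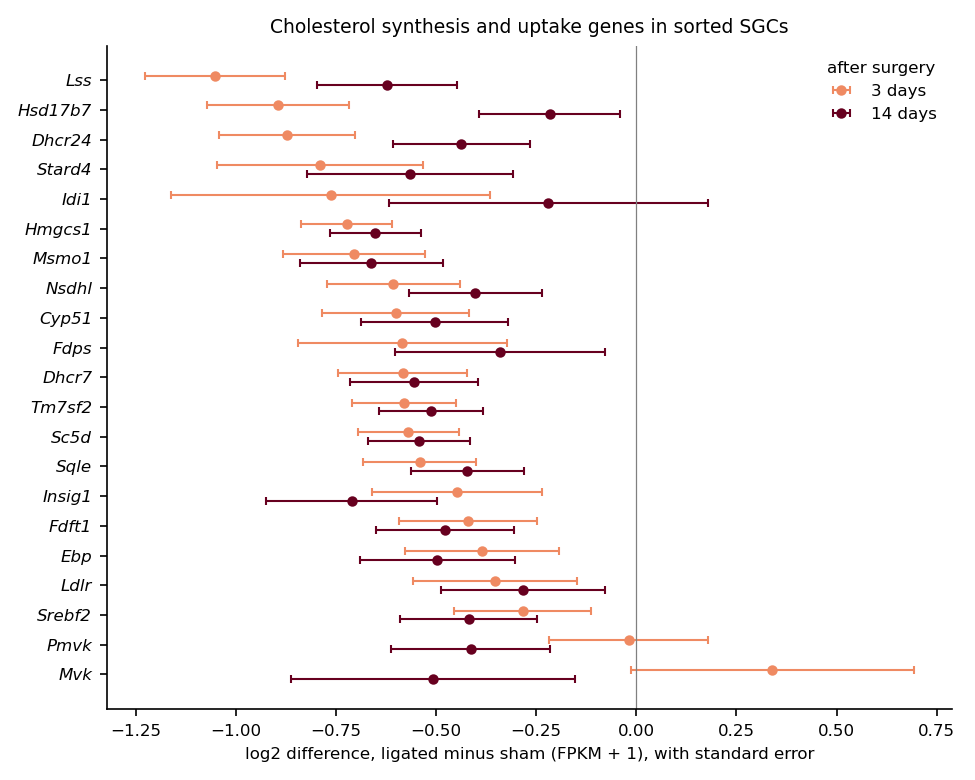
Points are log2 differences between ligated and sham SGCs for 21 of the 22 tested cholesterol genes (1 is not shown), with standard errors, at 3 days (orange) and 14 days (dark red). Differences of the genes shown are negative except for Mvk at 3 days, with Lss at −1.05 and Hmgcs1 at −0.72 at 3 days.

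Immune gene groups leaned higher at 14 days. Of 11 antigen presentation genes 4 rose adjusted over the list alone and none over all genes, with 10 positive (median 0.55; camera adjusted p = 3.5e-10, adjusted p = 0.0502 with an estimated correlation). B2m was at 4337 ± 706 against 2936 ± 301 FPKM and the class I gene H2-K1 at 214 ± 45.5 against 150 ± 15.8 (n = 4 each). All 20 interferon response genes were positive, 1 of them past the threshold adjusted over the list alone (median 0.49; camera adjusted p = 2.2e-09, adjusted p = 0.0916 with an estimated correlation), with Ifitm3 at 2313 ± 601 against 1615 ± 310 FPKM. Of 7 complement genes 2 rose adjusted over the list alone (median 0.48; camera adjusted p = 0.000392, adjusted p = 0.0515 with an estimated correlation). C4b was at 75.6 ± 19.1 against 41.7 ± 5.99 FPKM and the inhibitor Serping1 at 131 ± 23.3 against 81.5 ± 9.84 (n = 4 each). In the authors' deposited table B2m, C4b and Serping1 pass with log2 fold changes of 0.58, 0.93 and 0.72. Macrophage markers moved with these groups: all 6 were positive and 1 rose adjusted over the list alone (median 1.09; camera adjusted p = 0.00108, adjusted p = 0.0648 with an estimated correlation). They stayed low, with Lyz2 at 8.26 ± 3.1 against 6.07 ± 2.99 FPKM and Fcer1g at 5.97 ± 4.79 against 2.32 ± 3.48 (n = 4 each).

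Other lists passed camera at 14 days and lost the call with an estimated correlation. Endothelial markers were again positive in 10 of 10 (median 0.46; adjusted p = 0.000549, adjusted p = 0.253 with an estimated correlation), Egfl7 at 0.71. Fibroblast markers were positive in 6 of 7 (0.0485, and adjusted p = 0.333 with an estimated correlation) and cell cycle genes in 11 of 14 (0.00284, and adjusted p = 0.0648 with an estimated correlation). Satellite glial markers were negative in 13 of 15 (median −0.17, adjusted p = 0.000499; adjusted p = 0.253 with an estimated correlation), with Apoe at 5768 ± 956 against 7271 ± 631 FPKM (n = 4 each). Fatty acid synthesis genes were negative in 10 of 11 (median −0.17, adjusted p = 0.00284; adjusted p = 0.0844 with an estimated correlation) and mitochondrially encoded genes in 11 of 11 (median −0.12, adjusted p = 0.0101; adjusted p = 0.333 with an estimated correlation). Over 13924 genes limma called 1 (2 without ligated replicate 4, 2 with only the groups compared and 10 with array weights), and 718 had an unadjusted p under 0.05. The authors' deposited table holds 202 genes past 0.05, 123 higher and 79 lower after ligation.

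The difference between the effects at 14 and 3 days was tested directly. It was called for 1 gene, Polr2b (2.68, limma adjusted p = 0.000602), which is the gene listed at 0 in the ligated libraries of 3 days. Serpina3n had a difference of 0.72, Atf3 of −1.55 and Gal of −0.82, none near the threshold. In the simulated tables, this comparison recovered 5% of genes with a log2 difference of 1 and 54% of those with a difference of 2. Few calls therefore do not show that the effects at the 2 days are alike. Interferon genes leaned to 14 days in 18 of 20 members (median 0.46, camera adjusted p = 0.00195) and antigen presentation genes in 9 of 11 (median 0.26, 0.0126), with Ifitm3 at 0.55 and B2m at 0.18. Both lists had an adjusted p = 0.677 with an estimated correlation. Of 13924 genes, 584 had an unadjusted p under 0.05. Without ligated replicate 2 of 3 days the count was 2, and without ligated replicate 3 of 14 days it was 4. Sham SGCs at 14 against 3 days gave 0 called genes by limma, with 695 at an unadjusted p under 0.05. Among the genes the naming rule allows, the smallest p-values were those of Dnajc11, Nmnat1 and Bace1 (1.30, 1.44 and 0.80) and of Tsacc, Zfp748 and Phactr4 (−1.40, −1.28 and −1.34), and Fabp7 was at 0.23. Immediate early genes (median 0.42), satellite glial markers (0.15) and cholesterol genes (0.19) passed camera (adjusted p = 0.00135, 0.0251 and 0.0251). Each had an adjusted p = 0.731 with an estimated correlation.

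The neuron libraries ask what ligation changed in the neurons themselves at 8 days. Sprr1a (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895), a protein of regenerating axons, stood at 339 to 916 FPKM in the 6 ligated libraries and 0 to 96.5 in the 6 sham libraries, a log2 difference of 5.63 ± 0.61 (limma adjusted p = 0.000117). Neuropeptide Y, Npy (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507), stood at 22.6 to 162 against 0 to 2.63 FPKM (5.16 ± 0.47, adjusted p = 1.14e-05). Gal rose from 125 ± 50.2 to 1204 ± 604 FPKM (n = 6 each; 3.19, limma adjusted p = 0.000162) and Atf3 from 18.5 ± 11.6 to 157 ± 93.5 (3.15, 0.00178). Anxa1 rose by 3.66, the tubulin Tubb6 by 3.03, the receptor Cckbr by 2.99 and Tnni1 by 2.71. The authors' deposited table gives smaller fold changes for these genes, far smaller for all but Gal and Atf3. It does not pass 2 of them: Sprr1a is at 0.61 (adjusted p = 0.115) and Cckbr at 0.55 (0.192). No label or header says which neuron libraries or which form of estimate it rests on. The 2 sets of fold changes may therefore not be like measures. Npy is at 0.78 (0.0282) in the authors' deposited table, Anxa1 at 0.75 (0.0409), Tubb6 at 1.20 (0.000989) and Tnni1 at 0.99 (0.00836), while Gal and Atf3 are at 2.72 and 2.27. Among genes above 0 in every library, Stmn4 rose by 2.02, the guidance protein Sema6a by 1.83, Flrt3 by 1.58 and Mmp16 by 1.55.

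Of 18 nerve injury response genes, 10 rose over all genes and 16 adjusted over the list alone, and all 18 were positive (median 1.57; camera adjusted p = 1.65e-60, adjusted p = 5.71e-05 with an estimated correlation). The authors' deposited table has 13 of them higher after ligation. Of 7 cytokine and chemokine genes 1 rose over all genes and 2 adjusted over the list alone (median 0.57; camera adjusted p = 2.77e-06, adjusted p = 0.00572 with an estimated correlation), Csf1, the macrophage growth factor, by 1.56. Repair Schwann markers had 1 member higher over all genes and 3 adjusted over the list alone of 5 (camera adjusted p = 0.000175, adjusted p = 0.0074 with an estimated correlation). Its called gene is Gap43, at 479 ± 78.4 against 222 ± 58.8 FPKM (n = 6 each), which neurons also make and which is on the injury list. Reactive glia genes had 2 of 7 higher adjusted over the list alone (median 0.42; camera adjusted p = 7.37e-05, adjusted p = 0.0145 with an estimated correlation). Interferon genes had 2 of 18 higher adjusted over the list alone and 17 positive (median 0.46; camera adjusted p = 2.42e-07, adjusted p = 0.0893 with an estimated correlation), and immediate early genes 1 of 11 (camera adjusted p = 8.22e-05, adjusted p = 0.104 with an estimated correlation). The cytokine list shares Csf1 with the injury list, and the repair Schwann list shares Gap43, Jun and Bdnf. The immediate early list shares Atf3 and Jun with the injury list, so none of these lists is separate from it.

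**Figure D4:**
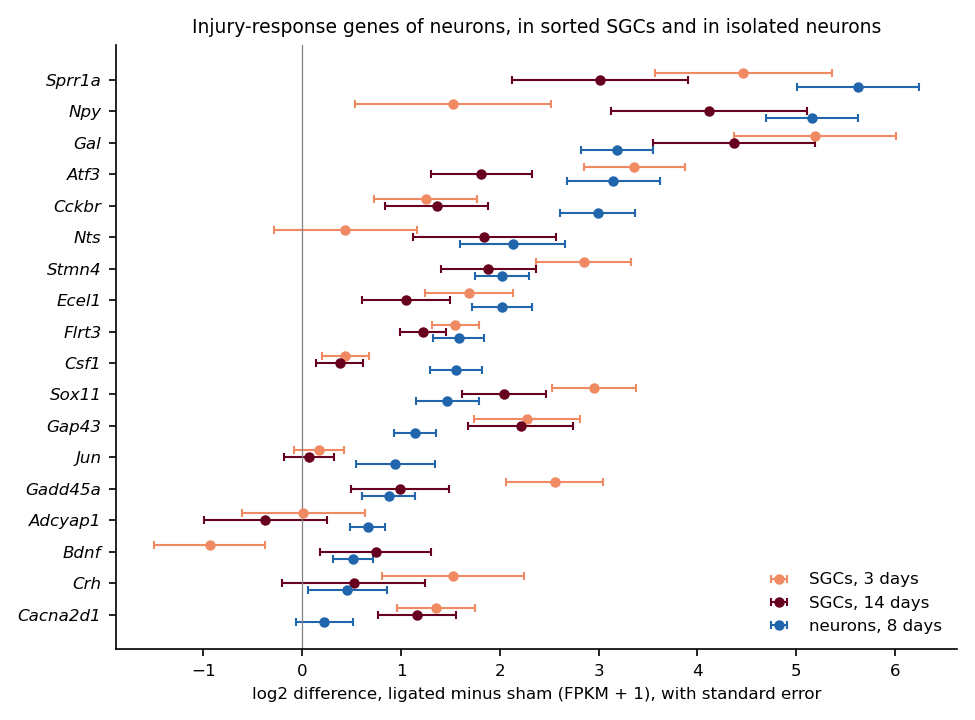
Points are log2 differences between ligated and sham libraries, with standard errors, for 18 nerve injury response genes in SGCs at 3 days (orange), SGCs at 14 days (dark red) and neurons at 8 days (blue). List medians are 1.54, 1.29 and 1.57; the SGC and neuron tables were scaled separately and come from different ligations.

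Neuronal identity genes were not called in neurons after ligation. Ion channels and receptors were negative in 15 of 17 (median −0.23; camera adjusted p = 0.0257, adjusted p = 0.31 with an estimated correlation), Scn10a at 143 ± 29.4 against 180 ± 27.3 FPKM (n = 6 each). Calca was at 0.39 and Tac1 at 0.35. Cholesterol genes were positive in 11 and negative in 12 of 23 (median −0.01, camera adjusted p = 0.635). Plin2, which coats lipid droplets, was at 86.5 ± 11.2 against 49 ± 11.8 FPKM (n = 6 each; 0.83, limma adjusted p = 0.738). Mitochondrially encoded genes were negative in 11 of 11 (median −0.61; camera adjusted p = 0.0234, adjusted p = 0.599 with an estimated correlation), with mt-Nd1 at 936 ± 691 against 1539 ± 1204 FPKM. Over 12145 genes limma called 34 higher and 0 lower, with 435 at an unadjusted p under 0.05. The authors' deposited table holds 237 genes past 0.05, 192 higher and 45 lower after ligation, and 27 of the 34 genes called here are among them. The count was 21 without the ligated male library 256191, and lower still in the fit on genes above 0 in every library.

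The sexes were compared in the same neurons. In females limma called 18 genes higher and 0 lower (306 at an unadjusted p under 0.05), among them Sprr1a (6.97), Npy (5.45), Anxa1 (4.36), Atf3 (4.05), Cckbr (3.84), Gal (3.32), Trp53i11 (3.00), Sez6l (3.00), Ecel1 (2.78), Stmn4 (2.41), Sema6a (2.06) and Csf1 (2.01). In males limma called 1, Npy (4.87, adjusted p = 0.00638; 322 at an unadjusted p under 0.05), and Atf3 was at 144 ± 115 against 24.5 ± 5.83 FPKM (n = 3 each; 2.25). With only the compared groups in the fit the female count was 5 (4 higher, 1 lower) and with array weights 35. Without the female library 260144 the count of 18 was 7, and without 255179 it was 11. The male call was lost with a pseudocount of 0.1 and with only the compared groups in the fit, and quantile normalization gave 2. The male count was 0 without 256191, 250119 or 257108, 3 without 252143 and 4 without 254167. Of 18 nerve injury response genes, 9 rose in females over all genes and 16 adjusted over the list alone, against 1 and 10 in males (camera adjusted p = 4.53e-62 and 4.19e-30; adjusted p = 4.92e-05 and 0.00246 with an estimated correlation). The difference between the sexes gave 0 called genes by limma, with 130 at an unadjusted p under 0.05. Among the genes the naming rule allows, its smallest p-values were those of Gas2, Cib1 and Bcl3 (2.06, 1.21 and 1.79) and of Rab3gap2, Cacng3 and Nmd3 (−1.18, −2.48 and −1.46), and Atf3 was at 1.81. Nerve injury response genes leaned to females in 16 of 18 (median 0.71, camera adjusted p = 1.72e-06; adjusted p = 0.323 with an estimated correlation). In the simulated tables, this comparison recovered 0% of genes with a log2 difference of 1 and 47% of those with a difference of 2. The sex labels were checked: Ddx3y was at 7.4 to 20.3 FPKM in the 6 male libraries and at most 0.0169 in the 6 female ones.

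**Figure D5:**
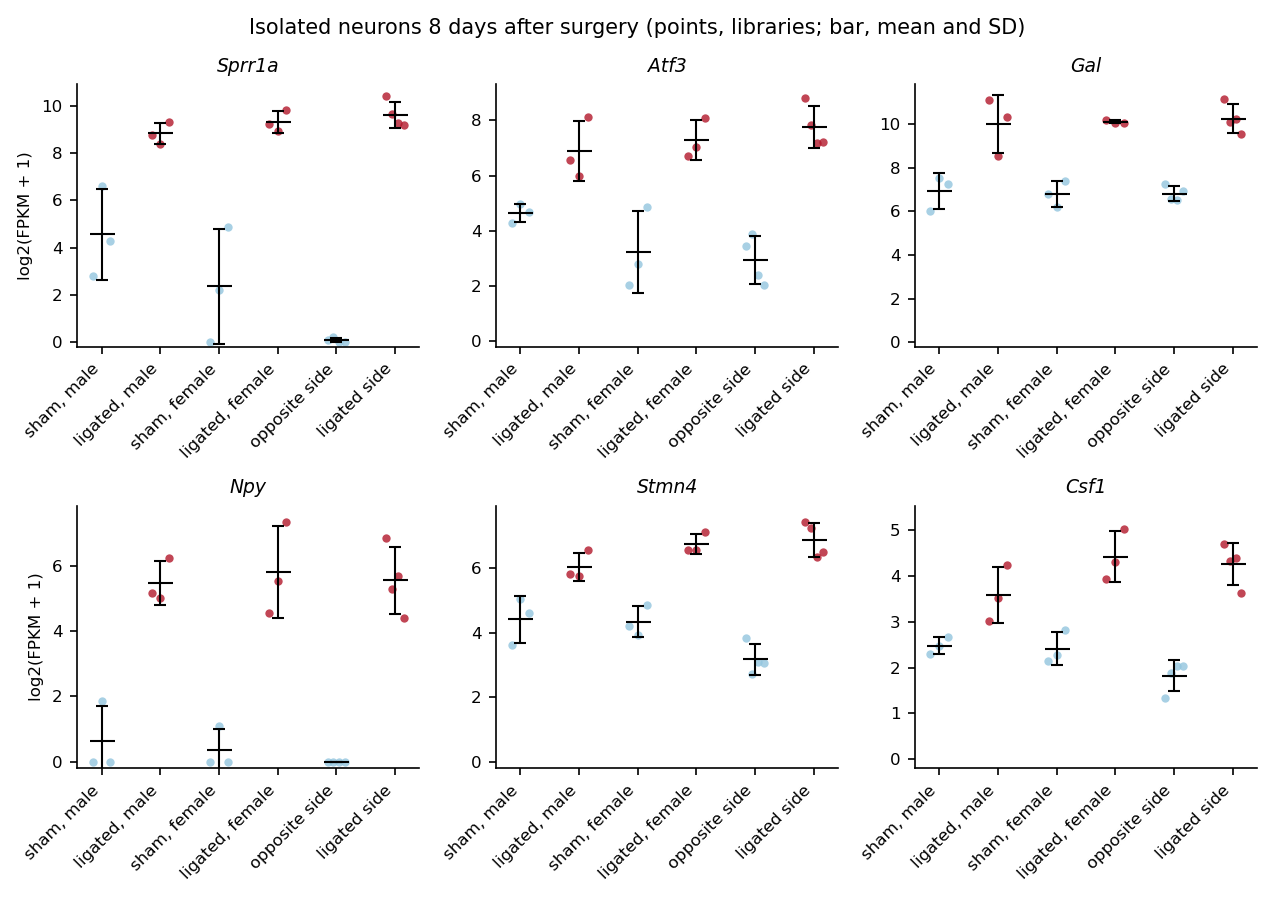
Points are log2(FPKM + 1) of single neuron libraries 8 days after surgery, by sex and surgery (n = 3 each) and by side in ligated mice (n = 4 each); black bars are mean and SD. Sprr1a is at 587 to 1362 FPKM on the ligated side and at most 0.144 on the opposite side.

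Within ligated mice, neurons of the ligated side were set against those of the opposite side. Sprr1a was at 587 to 1362 against 0 to 0.144 FPKM (9.56, limma adjusted p = 1.04e-06). Anxa1, Npy and Cckbr were at 35.5 to 176, 20.2 to 117 and 13.6 to 35.1 FPKM and listed at 0 in all 4 libraries of the opposite side. Atf3 stood at 241 ± 142 against 7.76 ± 4.96 FPKM (n = 4 each; 4.81, limma adjusted p = 0.000103), and Gal at 1332 ± 663 against 114 ± 28.4 (3.45). Bcat1 rose by 4.67, Tubb6 by 4.26, the receptor Gpr151 by 4.08, Nts, which encodes neurotensin, by 3.98, Ecel1 by 3.82, Stmn4 by 3.71, Serpinb1a by 2.89, Chac1 by 2.76, Wisp1 by 2.54 and Gap43 by 1.76. The 1 gene that fell was Trit1, by 1.73.

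Of 18 nerve injury response genes, 13 rose over all genes and 17 adjusted over the list alone (median 2.34; camera adjusted p = 8.13e-45, adjusted p = 0.000311 with an estimated correlation). Of 7 cytokine and chemokine genes 2 rose over all genes and 3 adjusted over the list alone, Csf1 by 2.45 and the alarmin Il33 by 1.44 (camera adjusted p = 1.15e-05, adjusted p = 0.00799 with an estimated correlation). Repair Schwann markers had 1 member higher over all genes, again Gap43, and 3 of 5 adjusted over the list alone (camera adjusted p = 0.000797, adjusted p = 0.0126 with an estimated correlation). Immediate early genes had 1 of 11 higher over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000364, adjusted p = 0.149 with an estimated correlation). As in the comparison with sham, the cytokine, repair Schwann and immediate early lists share members with the injury list, Csf1 among them. Interferon genes were positive in 15 of 18 (camera adjusted p = 0.00364, adjusted p = 0.406 with an estimated correlation) and fatty acid synthesis genes negative in 11 of 11 (0.0399, and adjusted p = 0.149 with an estimated correlation). Nociceptor markers were negative in 10 of 13 (median −0.39; camera adjusted p = 0.00985, adjusted p = 0.076 with an estimated correlation). Scn10a was at 119 ± 25.3 against 178 ± 24.3 FPKM and Scn11a at 102 ± 12.6 against 141 ± 16.1 (n = 4 each). Fatty acid oxidation genes had none called over all genes and 3 of 8 higher adjusted over the list alone (camera adjusted p = 0.0313, adjusted p = 0.406 with an estimated correlation), with Plin2 at 79 ± 13.6 against 36.4 ± 20.5 FPKM (n = 4 each). The endothelial gene Egfl7 was at 24.4 ± 10.2 against 61.9 ± 35.9. Over 12145 genes limma called 80 higher and 1 lower, and 1196 had an unadjusted p under 0.05. With only these 8 libraries in the fit the count was 30, all higher. Library 244142 of the opposite side was the poorest of the 8. It had 10225 genes at 1 FPKM or more and a mean r of 0.8425 with its group. In it, 28 of 3780 genes with a median of at least 20 FPKM were listed at 0.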

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

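In this part the tests that weigh an explanation were chosen only after the result was seen, and the counts of other splits of the libraries were planned.

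Nerve injury response genes such as Gal and Atf3, which injured neurons switch on, were higher in ligated SGC libraries at both days (list medians 1.54 and 1.29). A larger share of neuronal RNA after ligation would raise all neuron markers alike if injured neurons kept their levels of them. The 13 tested markers had medians of −0.15 (SD 0.507) at 3 days and 0.23 (SD 0.431) at 14 days. This argues against a larger share only on that condition, since no neurons of this ligation and these days were profiled. RNA of injured neurons carried at a constant share into the sorted libraries cannot be told apart from expression by SGCs. Across the 8 ligated libraries, centred within day, neuron markers and injury genes had Pearson r = 0.812 (one-sided permutation p = 0.0573) and Spearman rho = 0.595 (p = 0.0938), and r = 0.132 without the 2 farthest libraries, so the relation rests on those 2, and it was closer within 14 than within 3 days (4 libraries each). At 3 days the rise in SGCs was a median of 0.459 of the rise in neurons over 10 injury genes (0.0653 to 1.23), while neuron markers stood at a median of 0.0551 of their neuron level (0.0135 to 0.139), and at 14 days the medians were 0.404 and 0.063, but the neuron profile comes from another surgery, day and table.

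Several genes were listed at 0 in every library of 1 group and well above 0 in the other, Polr2b among them, whose effect differed between 14 and 3 days (2.68). Of 7 genes of this kind in SGCs at 3 days, the 3 with a baseMean of at least 100 in the authors' deposited table had a median absolute log2 fold change of 0.311 there, as failed estimates in the FPKM table would give, with Polr2b at −0.31, Gabpb2 at −0.15 and Nqo2, which leans the same way as its FPKM values, at −0.92 (adjusted p = 0.0726). Among genes with a lower baseMean, the authors' deposited table passes 2200002D01Rik at 3 days (4.87, adjusted p = 0.032) and Gm13840 at 14 days (−6.84, 0.0037), and for these the explanation is not borne out. In naive DRGs 15 named genes at 5 FPKM or more in every SGC library were listed at 0 in every ganglion library. With the lowest ratio of ganglion to SGC seen among satellite glial markers (0.278), all 15 would have stood at 1.49 FPKM or more, so these may be failed estimates too, and no biological explanation was tested.

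Antigen presentation, interferon and complement genes leaned higher in SGCs at 14 days, and macrophage RNA in the ligated libraries is a candidate explanation. The 15 macrophage markers rose by 21.1 FPKM in sum (SE 8.79), while B2m of class I rose by 1401 (SE 384). This argues against macrophages for the rise of B2m, the only class I gene weighed. H2-K1 rose by far less in FPKM (214 ± 45.5 against 150 ± 15.8, n = 4 each). No macrophage profile was at hand to give the expected ratios, so the rest of class I stays open. For class II the explanation stays open: macrophage markers had a median of 1.09 (SD 0.542) and the 4 class II genes, H2-Aa, H2-Ab1, H2-Eb1 and Cd74, a median of 1.70, and these genes are near the floor. A first, looser rule had excluded macrophages for class II, and a gap beyond both spreads was required only after that. Endothelial markers leaned higher at 14 days as well, and RNA of cells other than macrophages was not weighed. The labels do not name the antibodies of the sort, and expression by SGCs themselves was not tested.

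The effect of ligation differed between days for interferon response genes (median 0.46) and antigen presentation genes (0.26), and the call was lost for both with an estimated correlation (adjusted p = 0.677). Between the sexes it differed for nerve injury response genes (0.71), immediate early genes (0.85, with Atf3 and Jun on both lists), cholesterol genes (−0.25) and fatty acid oxidation genes (−0.26). With an estimated correlation these had adjusted p of 0.323, 0.38, 0.29 and 0.555.

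Single libraries lay far from the others of their group in 13 of 256 checks, where chance alone gives about 12.8. In DRG replicate 4 these were Kcnj10 (31.9 FPKM), Lamc1 (38.8), Htr3a (12.6) and Fos (494). The others were Cdh19 in naive SGC replicate 2 (46.5), Lss in ligated SGC replicate 4 at 3 days (12.5), Kcnj10 in ligated replicate 3 (44.5) and sham replicate 1 (50.9) at 3 days, Atf3 in sham replicate 1 at 14 days (2.75), and Plin2 in library 241106 of the ligated side (99.3). DRG replicate 2 had 12876 genes at 1 FPKM or more and 27.1% of its sum in the top 10 genes, and library 246166 of the ligated side had 10488 genes at 1 FPKM or more.

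The authors' deposited table that names no comparison holds 562 genes past an adjusted p of 0.05, 152 positive and 410 negative. Its comparison is unknown, so the table was used in none of the comparisons above.

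Other splits of the same libraries into groups of the same sizes were counted with only the compared libraries in the fit. Chance is unlikely for naive SGCs against DRGs (5789 genes, 1 of 35 splits as large, the real one, highest other 8). The same holds for the 2 sides of ligated mice (30 genes, 1 of 35, highest other 5). A share of 1 of 35 is the smallest these splits can give. It was not adjusted over the comparisons, and libraries may share animals, so chance is not strictly excluded. Neurons over both sexes had 31 genes, and 4 of the 100 splits counted, of 200 possible, were as large, the real one included. That share of 4 in 100 is under 0.05, but another split called 936 genes, many times the real count. Chance can therefore not be called unlikely there. A structure of the samples that does not follow surgery may lie behind that split, and this was not tested. Chance cannot be excluded for SGCs at 3 days (4 genes, 8 of 35, highest other 7), SGCs at 14 days (2 genes, 25 of 35, highest other 7), the difference between the days (1 gene, 39 of 100, highest other 3) or sham SGCs between days (1 gene, 29 of 35, highest other 11). For the difference between the sexes the real count is 0 by limma, so each of the 100 splits is as large by construction and the count says nothing about chance (highest other 1108). Males (0 genes by limma, so 10 of 10 by construction, highest other 147) and females (5 genes, 3 of 10, highest other 12) have too few splits for a share under 0.05.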

How the results depend on the processing

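The fit on genes above 0 in every library was chosen after seeing the data, and the other alternatives were planned. For the genes named in the text, 1118 results under alternatives other than leaving out a library kept their direction and side of the threshold, 53 lost and 2 gained the call, and 1 reversed. Leaving out libraries gave 1387, 87, 1 and 1. No gene list reversed. Camera with an estimated correlation called 0 of the 28 lists in the naive comparison, where the preset correlation called 19, and 2 of 26 against 8 in SGCs at 3 days, 3 of 26 against 13 at 14 days, and 4 of 23 against 8 in neurons over both sexes. Fry called 22, 5, 6 and 4 lists in these 4 comparisons, 1 of 23 in males, 3 in females, 6 between the sides, and 0 in the 2 differences of effects and in sham SGCs between days.

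The naive count stayed between 4146 and 6453 under the alternatives and between 4594 and 5909 without any 1 library, and a fold of at least 2 left 3116 genes. Counts in SGCs moved more, and the cause was not tested except where fewer genes were in the fit. At 3 days the 9 genes became 14 with a pseudocount of 0.1, 1 with no filter on low values, 5 with array weights, 4 with only the groups compared, 1 with the replicate number as a block, and 179 in the authors' deposited table. Without sham replicates 1, 2, 3 and 4 they were 5, 1, 1 and 5, and without ligated replicates 2, 3 and 4 they were 4, 3 and 1, a range of 1 to 6 over all libraries. At 14 days the 1 gene became 10 with array weights, 2 with only the groups compared, 0 with the replicate block by limma, where Serpina3n loses its call, and 202 in the authors' deposited table. It ranged from 1 to 2 without 1 library, with 2 without ligated replicate 4. The difference between the days had 0 genes with the replicate block and 0 among genes above 0 in every library, and ranged from 1 to 4 without 1 library (2 without ligated replicate 2 of 3 days, 4 without ligated replicate 3 of 14 days). Gal in that difference turned from −0.82 to 0.10 without sham replicate 2 of 3 days, and was at its lowest, −1.63, without sham replicate 4 of 3 days. Sham SGCs between days had 1 gene with only the groups compared and 0 to 1 without 1 library, with 1 without sham replicate 1 of 3 days. Fabp7 there turned from 0.23 to −0.11 with quantile normalization.

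In neurons over both sexes the 34 genes became 19 among genes above 0 in every library and 237 in the authors' deposited table, and 21 to 39 without 1 library, with 21 without the ligated male library 256191. In males the 1 gene became 0 with a pseudocount of 0.1, 2 with quantile normalization, 0 with only the groups compared, and 0 to 4 without 1 library. It was 3 without library 252143, 4 without 254167, and 0 without 256191, 250119 or 257108. In females the 18 genes became 35 with array weights, 5 with only the groups compared, 6 among genes above 0 in every library, and 7 to 18 without 1 library, with 7 without 260144 and 11 without 255179. The difference between the sexes had 0 genes by limma under each alternative and 0 to 1 without 1 library, with 1 without 258120. The 81 genes between sides became 30 with only the groups compared, 38 among genes above 0 in every library, and 62 to 119 without 1 library.

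No replicate block was run in neurons. No paired analysis was run, because the columns of the neuron table carry no replicate number and no label says which libraries share an animal. In SGCs and DRGs libraries with the same number were not closer to each other than to the others throughout (r from −0.076 to 0.186). Alternatives that need read counts were not run, since none are deposited, and neither was a count from the authors' tables for the naive comparison. Depth limits cannot be given without counts.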

Other observations

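The tests in this part were chosen only after the results were seen. Neurons at 8 days gave 32 genes that were called after ligation and could be looked up in SGCs, and these leaned higher in ligated SGCs as well: 28 had a positive difference at 3 days (median 1.03) and 29 at 14 days (median 1.13), and 4 and 0 of them passed over all genes. Beyond the injury genes on the lists, Sez6l stood at 1.36 and 1.71 in SGCs at 3 and 14 days, Sdc1 at 1.20 and 1.73, the galectin Lgals1 at 1.19 and 1.14, Mmp16 at 1.04 and 1.28, and Anxa1 at 2.14 and 1.02. Cd63 (−0.17 at 3 days) and Phgdh (−0.09 and −0.60) did not follow.

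A hypothesis was that the genes on no fixed list also move together in SGCs. The 22 such genes, which are among the 32 above and so are no separate evidence, had a median of 0.87 at 3 days, 18 positive, and 0.62 at 14 days, 19 positive, and 0 of 10000 random lists matched in expression had a median as high at either day. Random lists ignore correlation between members, and camera on the 22 genes gave adjusted p = 0.008 at each day with an estimated correlation of 0.123. None of the 22 was called in SGCs at 3 days by limma. This may reflect RNA of injured neurons or a response that SGCs share, and the values here do not part the 2.

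The authors' deposited table that names no comparison was set against differences between groups across 10498 genes. Its log2 fold changes had r = 0.444 with naive SGCs minus DRGs, and 0.636, 0.496, 0.818 and 0.525 with naive SGCs minus ligated at 3 days, sham at 3 days, ligated at 14 days and sham at 14 days, tables that were scaled separately.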
